A study of Mus musculus with 7 samples.

How the data were processed

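RNA was measured in gastrocnemius, the fast calf muscle, of mice whose limb had been immobilized. The 7 libraries came from 4 samples of a knockout of DJ-1 (gene Park7) restricted to skeletal muscle and from 3 samples of the floxed control, which the labels also call wild type. Both groups were immobilized and no library came from a free limb, so the comparison made was knockout minus control and the effect of immobilization itself could not be tested. The labels do not state that each library is a separate animal, so every p-value measures the spread between samples only.

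Per the labels, the libraries were read on a BGISEQ-500 as 150 bp paired ends at an intended depth of 30 M reads. The authors aligned the reads to mm10 with STAR 2.7.10a, quantified genes with RSEM 1.2.28 and tested them with DESeq2 (version given as 1.3.40), calling genes at an adjusted p of 0.05 and a 1.5-fold change. The deposited table gives RSEM expected counts per gene, which were rounded to whole numbers before testing. An expected count that is not whole marks reads shared between similar genes. The transcript annotation, the strand of the protocol and the exons removed in the knockout are not given in the sources used here. The table held 21487 genes identified by symbol alone, of which 18383 matched a single gene of GENCODE M21 on GRCm38, the source of positions, GC content and length. Spreadsheet software had turned 24 symbols into dates, and such genes were tested but not named. The mRNAs of mitochondrial DNA carry their own names in the table (COX2 is there a subunit of cytochrome c oxidase).

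Library totals ran from 24458343 to 26389010 counts. Simulated counts of this size and design had 200 changed genes and the proteasome list shifted by 1.5-fold, with variation set by the average level of each gene only. Outside that list the test recovered 39.1% of genes changed 1.5-fold, 81.2% of those changed 2-fold and 100% of those changed 4-fold. Of all its calls 3.55% were unchanged genes. The data had 1998 calls, far more than the genes changed in the simulation, so these shares may differ here. The table is the only data file and all 7 columns of counts were used.

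Genes were tested in R 4.3.3 with edgeR 4.0.16, after filterByExpr with its default settings and TMM normalization, by the quasi-likelihood F test without a robust prior. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Standard errors are the absolute log2 fold change over the square root of F. Levels are counts-per-million (CPM) on TMM library sizes, as mean ± SD. Log2 CPM for list tests and principal components used a prior count of 2. A gene's groups were called separated where every knockout library lay beyond every control library.

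Before the data were examined, 39 gene lists were fixed: atrophy genes, autophagy and lysosome, proteasome, nuclear subunits of complex I, of complexes II and III, of complex IV and of ATP synthase, mitochondrial DNA mRNAs, mitochondrial biogenesis and dynamics, tricarboxylic acid cycle, fatty acid uptake and oxidation, glycolysis and glycogen, antioxidant and NRF2 targets, integrated stress response, ER chaperones, denervation and neuromuscular junction, slow and fast fibre contractile genes, IGF1-mTOR and protein synthesis, cytosolic ribosomal proteins, extracellular matrix, inflammatory cytokines, interferon response, cell cycle, immediate early genes, heat shock, circadian clock and sex-linked genes. The others were markers of macrophages, neutrophils, lymphocytes, fibroblasts and their progenitors, satellite cells, endothelium, pericytes and smooth muscle, adipocytes, Schwann cells, tenocytes and erythroid cells. The 37 lists with at least 3 tested genes were compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over those lists, and again with an estimated correlation. Whether a list's genes move on balance one way was tested by fry.

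The genes to name were also set by rule before the data were examined. The rule took Park7, Fbxo32, Trim63, Foxo1, Foxo3, Mstn and Ppargc1a always. It added the 10 largest rises and 10 largest falls among called genes with an average log2 CPM above 1, separated groups and an established symbol, then up to 4 called members of each list with the smallest p, or 2 members where none was called. Myh7 and Per3 were added after their values had been seen, which makes 142 genes. Members named only to spell out a small count were also picked after their values had been seen.

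Library measures were compared by a 2-sided exact permutation test over the 35 splits of 7 libraries into 3 and 4, whose smallest p is 0.0286. The number of called genes and lists was recomputed for all 35 splits. The counts of called genes and lists, the list tests and the named genes were recomputed under alternatives. These were RLE or upper quartile scaling, no filter, a mean count of at least 10, DESeq2 1.42.0, limma voom and a robust prior. Further ones were a term for the replicate number on replicates 1 to 3, and each library left out in turn. The count of genes was also taken with edgeR's glmTreat at 1.2-fold. Offsets for GC content and length, and leaving out the mitochondrial DNA mRNAs with the 10 most abundant nuclear genes, were alternatives chosen after seeing the data. List tests by camera were also run with a prior count of 0.5 and on ranks. Other alternatives on the pseudocount were not run, since they apply to normalized values.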

Results

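Gene expression was measured in the immobilized gastrocnemius of mice that lacked DJ-1 in skeletal muscle (4 libraries, knockout 1 to 4) and of floxed controls (3 libraries, control 1 to 3). DJ-1, the product of Park7, is a protein that protects cells from oxidative stress and is mutated in some familial Parkinson's disease. The comparison addressed which genes differ between knockout and control muscle under disuse. It cannot separate the loss of DJ-1 from any other difference between the 2 groups. The controls held 24458343, 26278940 and 26389010 counts and the knockouts 25733722, 26085765, 26052876 and 25651559. No difference in totals was detected by an exact permutation test (p = 0.914). The controls held 18092 ± 135 genes with a count (SD, n = 3) and the knockouts 17605.5 ± 171 (SD, n = 4), without overlap (exact permutation p = 0.0571, and 0.0952 adjusted over 5 library measures). The 10 most abundant genes took 26.2% ± 0.470 and 27.4% ± 2.37 of the counts (exact permutation p = 0.457).

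Park7 itself fell in every knockout library. Its level was 245 ± 18.8 CPM in the controls (SD, n = 3) and 37.3 ± 2.94 CPM in the knockouts (SD, n = 4), which is 0.152 times the control level. The log2 fold change was -2.71 (SE 0.0895, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.52e-06). The controls read 240, 229 and 266 CPM, from 5961, 5987 and 6884 counts. The knockouts read 35.9, 41.5, 34.7 and 37.2 CPM, from 990, 1090, 872 and 923 counts. The gene lies on the minus strand of mouse chromosome 4, at 150897133 to 150914437 in GRCm38. Whole muscle holds cells other than fibres, in which a knockout restricted to skeletal muscle leaves the gene in place.

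The muscles without DJ-1 had more RNA of the ubiquitin ligase genes Fbxo32 and Trim63, which mark atrophy. Whether this rise reflects more wasting or another mix of fibres was not tested. Lists of genes for mitochondrial respiration, fat oxidation, slow fibres and extracellular matrix lay lower than other genes by camera with the preset correlation, calls that were lost with an estimated correlation (adjusted p = 0.277 to adjusted p = 0.384). Of 13409 genes tested, 1998 changed, 895 of them higher and 1103 lower in the knockout. By more than 1.5-fold, 296 genes rose and 713 fell. The groups were separated in 1949 of the called genes, and in 3860 of all tested genes, where chance gives 5.71%. The split depended on scaling: 44.8% of calls were higher with TMM and 33.2% with upper quartile scaling. The first principal component held 45.3% of the variance and set all knockouts apart from all controls, whereas the second (16.4%) set knockout 2 apart. The number of calls moved by more than 1.5 times without control 1 (830), control 2 (1040), control 3 (793), knockout 3 (952) or knockout 4 (1253). Calls over 1.5-fold numbered 595 without control 1, 582 without control 3 and 590 without knockout 3, against 1009 with all libraries.

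Fbxo32 and Trim63, ubiquitin ligase genes of muscle wasting, rose in the knockout. Fbxo32 (atrogin-1), which marks muscle proteins for breakdown, rose from 460 ± 113 CPM (SD, n = 3) to 1069 ± 84.9 CPM (SD, n = 4), a log2 fold change of 1.22 (SE 0.163, adjusted p = 0.00452). Trim63 (MuRF1), the ligase of thick filament proteins, rose 2.58-fold, by 1.37 (SE 0.223, adjusted p = 0.00795). Mstn, which encodes myostatin, the inhibitor of muscle growth, rose by 0.79 (SE 0.157, adjusted p = 0.0146). Its call ended without control 1 (adjusted p = 0.0566) or control 3 (0.0613), and with a term for the replicate number (0.0531). Cdkn1a, an inhibitor of the cell cycle that is induced in wasting muscle, rose by 1.01 (SE 0.185, adjusted p = 0.0111). Foxo1 and Foxo3, transcription factors that drive the ligase genes, had log2 fold changes of 0.72 and 0.30 and did not pass (adjusted p = 0.115 and 0.140), although Foxo1 was called with DESeq2 (0.0454) and with a term for the replicate number (0.0265).

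Of the 34 atrophy genes tested, 12 rose and 1 fell, the ring-finger protein gene Trim55 (13 and 1 adjusted over the list alone). The list lay higher than other genes by camera (adjusted p = 0.000109), and not with an estimated correlation (adjusted p = 0.227). The number that rose was 7 without control 1 and 3 without control 3, and Trim55 was not called without any control, knockout 1 or knockout 4, when 0 genes fell. Ddit4 and Eif4ebp1 also belong to it, a brake on mTOR signalling and a repressor of translation. Ddit4 rose by 1.94 (adjusted p = 0.0167, which became 0.0563 without control 2 and 0.0656 without control 3). Eif4ebp1 rose by 1.10 (adjusted p = 0.0128, which became 0.0505 without control 3). The glucocorticoid receptor gene Nr3c1 rose by 0.42 (adjusted p = 0.0127, which became 0.0510 without control 3).

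**Figure D1:**
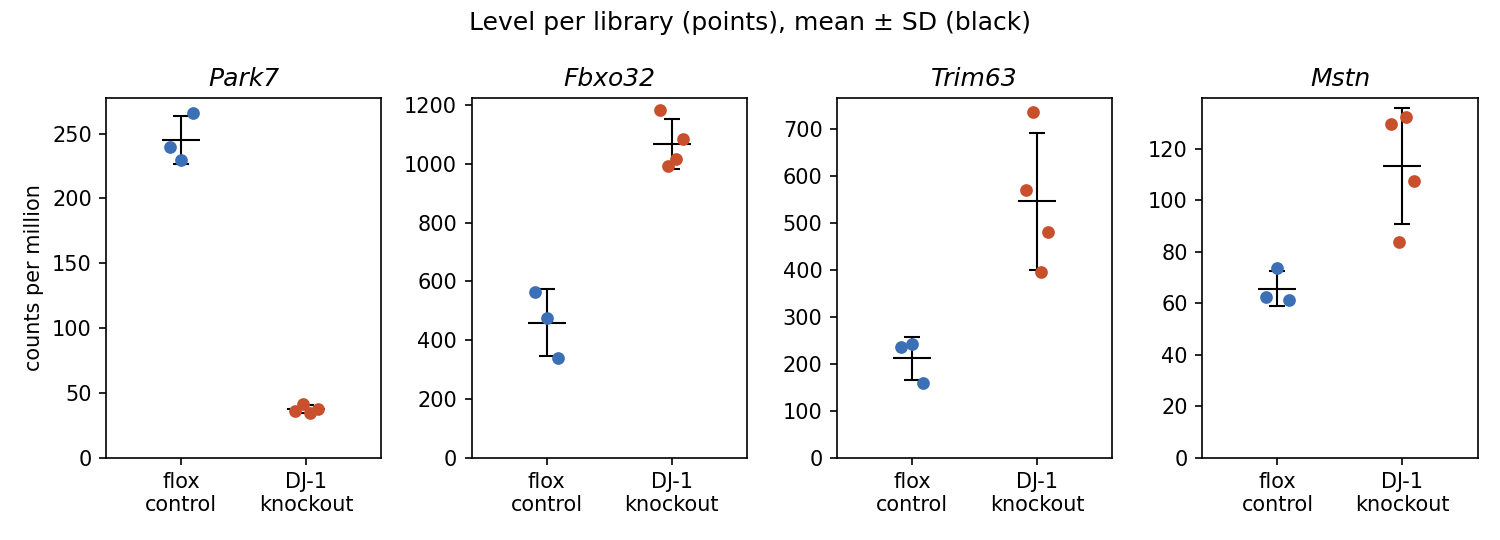
Levels of Park7, Fbxo32, Trim63 and Mstn in counts-per-million (CPM, y axis, from 0) in each control and knockout library (points), with the mean and SD of each group in black. The knockouts read 34.7 to 41.5 for Park7 against 229 to 266 in the controls, and for the other genes each knockout lies above each control.

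Among 33 proteasome subunits, 5 rose and none fell (6 and 0 adjusted over the list alone), among them Psmd8 by 0.54 (SE 0.127, adjusted p = 0.0253) and Psmd1 by 0.48 (SE 0.121, adjusted p = 0.0322). The subunits lay higher as a list (camera adjusted p = 3.00e-05, adjusted p = 0.522 with an estimated correlation). Without control 1, control 3 or knockout 3 no subunit was called, and 2 to 3 were called without any other library, in fits with fewer samples. With 1 library left out the log2 fold change ran from 0.42 to 0.68 for Psmd8 and from 0.41 to 0.54 for Psmd1. Psmd8 was called only without control 2 or knockout 2 (adjusted p = 0.0514 to 0.0862 without the others), and Psmd1 only without knockout 1, 2 or 4 (0.0753 to 0.122). Of 32 autophagy and lysosome genes, the autophagy receptor Optn rose by 0.44 and the protease gene Ctsb fell by 0.58 on the log2 scale (adjusted p = 0.0435 and 0.00663). The call of Optn held only without control 2 and was lost without each other library (adjusted p = 0.0662 to 0.151). Adjusted over the list alone 0 rose and 1 fell, and camera gave an adjusted p of 0.164. Ctsb has reads shared with similar genes.

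Of 23 genes of IGF1-mTOR signalling and protein synthesis, 6 rose and 0 fell, as they did adjusted over the list alone. They included the kinases Akt2 by 0.36 and Akt1 by 0.63 (adjusted p = 0.0139 and 0.0198), but also Mstn and Eif4ebp1, which restrain growth. Camera placed the list higher (adjusted p = 0.0176, adjusted p = 0.277 with an estimated correlation). Without control 1, 2 of its genes were called (Akt2 adjusted p = 0.0552, Akt1 0.0735), and without control 3 none was (0.0514 and 0.0610). Akt1 also lost its call without control 2 (0.0548). Among 44 cytosolic ribosomal proteins 1 rose, Rps18 by 0.34 (adjusted p = 0.0449, which kept its side only without control 2 and reached 0.164 without control 1), and 0 did adjusted over the list alone. The list median was 0.11 (0.064 without control 1 and 0.171 without control 2), with a camera adjusted p of 0.00288 that became 0.0638 without control 1, and adjusted p = 0.667 with an estimated correlation.

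RNA for mitochondrial respiration was lower in every knockout library. The mRNAs made from mitochondrial DNA took 18.6% ± 1.51 of all counts in the controls (SD, n = 3) and 10.4% ± 1.40 in the knockouts (SD, n = 4, exact permutation p = 0.0286, the smallest possible, and 0.0714 adjusted over 5 library measures). Of the 13 such mRNAs, 12 fell and none rose (13 adjusted over the list alone). ND3, a complex I subunit, fell by 0.90 on the log2 scale (SE 0.136, adjusted p = 0.00653). COX2, a subunit of cytochrome c oxidase, fell from 17930 ± 1574 to 9790 ± 1015 CPM, by 0.87 on the log2 scale (SE 0.155, adjusted p = 0.01). The 1 mRNA that did not pass was ND6, encoded on the other strand. The list median was -0.81 (camera adjusted p = 3.88e-11, adjusted p = 0.277 with an estimated correlation).

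Most subunits of the respiratory chain encoded in the nucleus also fell. Of the 79 tested, 64 fell and 0 rose. In complex I, which takes electrons from NADH, 26 of 36 subunits fell (30 adjusted over the list alone, median -0.37), among them Ndufs8 by 0.62 on the log2 scale (SE 0.0728, adjusted p = 0.00306) and Ndufs1. The number was 15 without control 1, control 2 or control 3 and 16 without knockout 3. In complexes II and III 12 of 13 fell (13 adjusted over the list alone, median -0.48), with Sdhb, the iron-sulfur subunit of succinate dehydrogenase, at -0.85 (SE 0.0904, adjusted p = 0.00269). In complex IV 12 of 15 fell (13 adjusted over the list alone, median -0.39), with the muscle isoform Cox7a1 at -0.80 (SE 0.0788, adjusted p = 0.00207). That number was 5 without control 1, 4 without control 2 and 7 without control 3 or knockout 3. In ATP synthase 14 of 15 fell, as they did adjusted over the list alone (median -0.42), with Atp5g3 at -0.55 (SE 0.0743, adjusted p = 0.00469). Camera gave adjusted p-values of 3.79e-12, 1.15e-08, 4.59e-08 and 1.58e-09 for these 4 lists, and each had an adjusted p = 0.277 with an estimated correlation.

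Most tested genes of the pathways that feed the respiratory chain fell as well. Of 20 genes of the tricarboxylic acid cycle and its entry, 18 fell (19 adjusted over the list alone, 10 without control 1), including the aminotransferase Got2 by 0.61 on the log2 scale (SE 0.072, adjusted p = 0.00306) and Idh3a, a subunit of isocitrate dehydrogenase, by 0.53 (SE 0.0693, adjusted p = 0.00429). Of 29 genes of fatty acid uptake and oxidation, 21 fell and 1 rose, the regulator Ppard (the same counts adjusted over the list alone). Acaa2, the last enzyme of mitochondrial beta-oxidation, fell from 135 ± 10.1 to 45.5 ± 7.91 CPM, a log2 fold change of -1.56 (SE 0.134, adjusted p = 0.00131). The fatty acid transporter Slc27a1 fell by 1.54 on the log2 scale (SE 0.176, adjusted p = 0.00298), and Etfdh, which passes electrons from fat oxidation to the chain, by 0.81 (SE 0.0848, adjusted p = 0.00239). The list medians were -0.44 and -0.70 (camera adjusted p = 3.88e-11 and 3.82e-12, adjusted p = 0.277 and adjusted p = 0.310 with an estimated correlation). The lone rise of Ppard was lost without any control, knockout 3 or knockout 4, when 0 genes of the list rose.

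Regulators of mitochondrial content were not called as a list, while some single genes fell. Ppargc1a (PGC-1alpha), the main regulator of mitochondrial biogenesis, stood at 37.7 ± 4.26 CPM in the controls and 39.9 ± 12.1 in the knockouts (adjusted p = 0.813). Of 26 genes of mitochondrial biogenesis and dynamics 4 fell and 0 rose (5 and 2 adjusted over the list alone, 11 at an unadjusted p under 0.05, camera adjusted p = 0.284). The fusion gene Mfn1 fell by 0.58 on the log2 scale (SE 0.0656, adjusted p = 0.00298) and was called without each library in turn. Sirt3, a mitochondrial deacetylase, fell by 0.48 (adjusted p = 0.0187), a call that ended without any control or knockout 3 (0.0513 to 0.0646). Perm1, a regulator of oxidative genes in muscle, and Ppargc1b (PGC-1beta) fell by 0.69 and 0.66 (adjusted p = 0.0406 and 0.0494), calls that ended without any library but knockout 2 (0.0682 to 0.111 and 0.0570 to 0.139). With 1 of those 6 libraries left out, 1 to 2 genes of the list fell.

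Some glycolysis and glycogen genes rose. Of 24 tested, 7 rose and 2 fell, Pgam2 and Pfkfb1 (9 and 2 adjusted over the list alone, median 0.31). Gpi1, glucose phosphate isomerase, rose from 842 ± 33.0 to 1374 ± 183 CPM, by 0.71 on the log2 scale (SE 0.117, adjusted p = 0.00812). The lactate exporter Slc16a3 rose by 0.65 (adjusted p = 0.0141, which became 0.0546 without control 1 and 0.0559 without control 3). Camera gave an adjusted p of 0.000900 (adjusted p = 0.277 with an estimated correlation). Without any 1 control 3 genes rose and 0 fell, and 0 or 1 fell without knockout 1, 3 or 4.

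**Figure D2:**
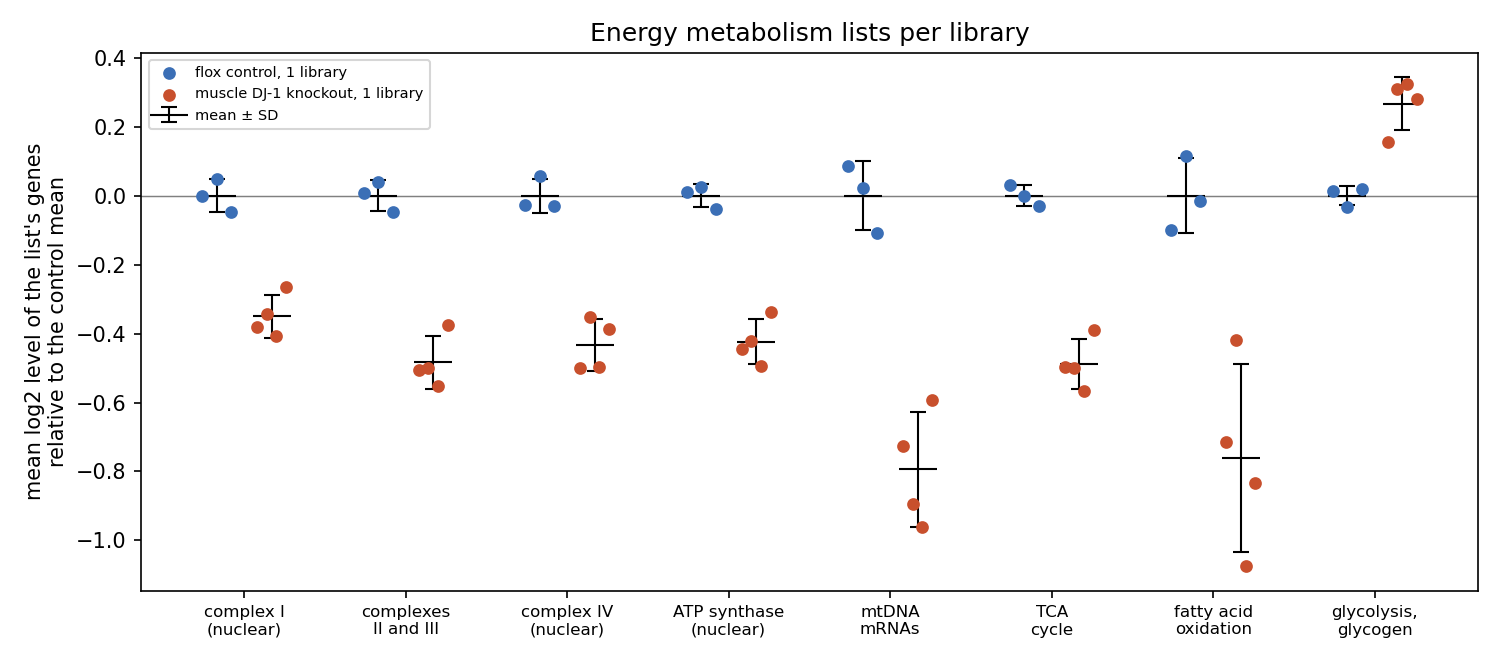
Mean log2 level of the genes of 8 energy metabolism lists relative to the control mean (y axis) in each control and knockout library (points), with the mean and SD of each group in black. In each of the 7 mitochondrial lists all knockouts lie below all controls, from -0.59 to -0.96 for mitochondrial DNA mRNAs, and in glycolysis and glycogen all knockouts lie above.

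Most slow fibre genes fell and the myosin of the fastest fibres rose. Of 15 slow fibre genes 9 fell and 0 rose (14 adjusted over the list alone), with a median of -2.08 (camera adjusted p = 1.53e-07, adjusted p = 0.310 with an estimated correlation). Casq2, the slow and cardiac calcium store protein, fell by 1.84 on the log2 scale (SE 0.242, adjusted p = 0.00427), and Fhl1, a scaffold protein of the sarcomere, by 2.11 (SE 0.331, adjusted p = 0.00717). Myh7b, a slow-type myosin, fell by 2.01 (SE 0.388, adjusted p = 0.0132). The number of slow genes that fell was 5 without control 1, 4 without control 2 and 5 without control 3. The knockouts were far apart: the list scores were -1.47, -2.88, -3.98 and -1.39 for knockout 1 to 4, against -0.21, 0.20 and 0.01 in the controls. Myh7, the slow myosin heavy chain, singled out after its values were seen, read 238, 9.29, 5.78 and 288 CPM in the knockouts against 723 ± 66.8 in the controls and did not pass (log2 fold change -2.42, SE 1.09, adjusted p = 0.165).

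Of 18 fast fibre genes 3 rose and 2 fell, as they did adjusted over the list alone, and camera gave an adjusted p of 0.0747 (0.0140 without control 3 and 0.00539 without knockout 1). Myh4, the myosin heavy chain of type IIb fibres, rose from 46309 ± 9386 CPM (SD, n = 3) to 99854 ± 23059 CPM (SD, n = 4), by 1.11 on the log2 scale (SE 0.296, adjusted p = 0.0380). It took 9.93% ± 1.91 of all knockout counts against 4.61% ± 0.864 (exact permutation p = 0.0286, and 0.0714 adjusted over 5 library measures). The heavy chains of type IIx and IIa fibres, Myh1 and Myh2, fell by 1.45 and 2.25 on the log2 scale (SE 0.357 and 0.65, adjusted p = 0.0292 and 0.0485). Actn3, the Z-disc protein of fast fibres, rose by 0.74 (SE 0.164, adjusted p = 0.0214), a call that ended without control 1 (0.0867) or control 2 (0.0738). The call of Myh4 ended without any library but knockout 1 (adjusted p = 0.0661 to 0.152) and that of Myh2 without any but knockout 3 (0.0553 to 0.117), where Myh2 read 124 CPM. Myh1 lost its call without control 1 (0.0714), control 2 (0.07), control 3 (0.0788) or knockout 1 (0.0622). These myosins are similar in sequence and share reads, which leaves their exact levels uncertain.

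**Figure D3:**
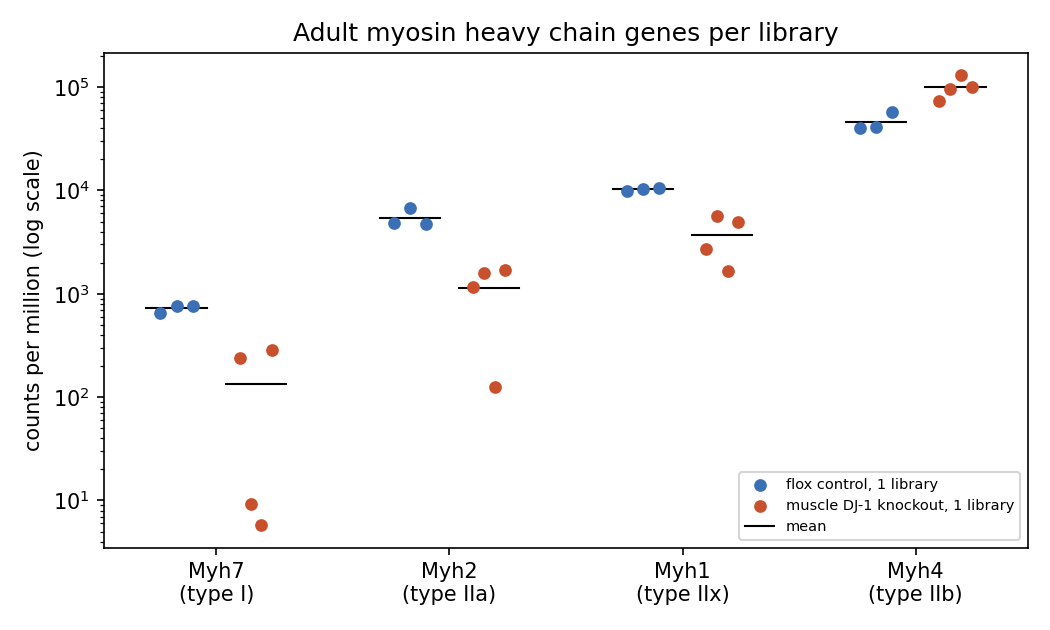
Levels of the adult myosin heavy chain genes in counts-per-million (CPM, y axis, log scale) in each control and knockout library (points), with group means as bars. Mean Myh4 is 99854 in the knockouts against 46309 in the controls, the knockouts lie below the controls for the other genes, and Myh7 in knockouts 2 and 3 is under 10.

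Some connective tissue genes fell in the knockout. Of 28 extracellular matrix genes 11 fell and 0 rose (16 adjusted over the list alone, median -0.78). Bgn, the matrix proteoglycan biglycan, fell by 1.41 on the log2 scale (SE 0.18, adjusted p = 0.00387). Postn, periostin, which is secreted in remodelling tissue, fell by 3.59 (SE 0.711, adjusted p = 0.0143) from 20.4 ± 20.2 to 1.66 ± 1.28 CPM, a log2 fold change that was -2.39 without control 3 and -4.30 without knockout 1. Its call ended with the term for the replicate number (adjusted p = 0.0807). Fn1, fibronectin, fell by 1.33 (SE 0.282, adjusted p = 0.0179, which became 0.0623 without control 1, 0.0661 without control 3 and 0.0507 without knockout 3). Camera gave an adjusted p of 1.41e-06 (adjusted p = 0.384 with an estimated correlation). The list median was -0.47 without control 3. The number that fell was 2 without control 1 or control 3, 5 without knockout 2 and 3 without knockout 3 or knockout 4. The list scores of the controls ran from -0.47 to 0.50 and those of the knockouts from -1.13 to -0.53.

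Some markers of fibroblasts, blood vessels, macrophages and fat fell. Of 12 markers of fibroblasts and their progenitors 4 fell (5 adjusted over the list alone), one of which, Col1a1, is also in the matrix list. They included the proteoglycan Lum, which fell by 1.46 on the log2 scale (SE 0.215, adjusted p = 0.00641) and the surface protein Cd34 by 0.60 (SE 0.118, adjusted p = 0.0140). Of 12 pericyte and smooth muscle markers 6 fell (7 adjusted over the list alone), including the pericyte proteoglycan Cspg4 by 0.71 (SE 0.115, adjusted p = 0.00781). Of 12 endothelial markers 2 fell (2 adjusted over the list alone), the receptor Tie1 by 0.47 and Egfl7 by 0.59 (adjusted p = 0.0162 and 0.0172). Of 15 macrophage markers 3 fell (6 adjusted over the list alone), including the growth factor receptor Csf1r by 0.94 (SE 0.126, adjusted p = 0.00452). Of 11 adipocyte markers 3 fell (4 adjusted over the list alone). They were the lipase Lipe by 0.73 (SE 0.137, adjusted p = 0.0124), Fabp4 by 0.54 (adjusted p = 0.0340) and Retn by 1.12 (adjusted p = 0.0456). Fabp4 and Retn each kept their call in only 1 of the 7 fits with a library left out. None of these markers rose.

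Camera placed those 5 lists lower, with adjusted p-values of 0.00848 for fibroblasts, 0.000794 for pericytes, 0.00969 for endothelium, 0.00280 for macrophages and 0.00639 for adipocytes. With an estimated correlation these became adjusted p = 0.547, adjusted p = 0.227, adjusted p = 0.384, adjusted p = 0.522 and adjusted p = 0.390. The fibroblast list lost its call without control 1 (adjusted p = 0.0638). Without control 1, 1 pericyte marker fell, without control 2 it was 3, without control 3 it was 1 and without knockout 4 it was 2. Of macrophage markers 1 fell without control 3, knockout 3 or knockout 4, and 5 without knockout 2. Of adipocyte markers 1 fell without control 1, control 3, knockout 2, knockout 3 or knockout 4. Of endothelial markers 1 fell without control 1 or control 2 and 0 without control 3 (Tie1 adjusted p = 0.0514, Egfl7 0.0667). Tie1 lost its call without control 1 (0.0543) and control 2 (0.0518) too.

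Some interferon response, Schwann cell and erythroid genes fell, with 1 control high in each list. Of 24 interferon response genes 5 fell (13 adjusted over the list alone, median -1.02), including Ifi27 by 0.64 on the log2 scale (SE 0.12, adjusted p = 0.0121). Gbp2, an interferon-induced GTPase, fell by 2.38 (adjusted p = 0.0479), with overlapping groups and control levels of 51.1, 9.35 and 4.71 CPM. Its log2 fold change was -0.76 without control 1, and it was not called without control 1 (0.155), control 2 (0.0513) or any knockout (0.0603 to 0.110). Of 10 Schwann cell markers 2 fell (6 adjusted over the list alone, median -1.27), including Pmp22, a membrane protein of peripheral nerve, at -1.39 (adjusted p = 0.0386). Of 7 erythroid genes 5 fell (7 adjusted over the list alone, median -1.43), including the globin Hba-a1 by 1.47 (adjusted p = 0.0407, which held only without control 2 or knockout 2 and reached 0.136 without control 3). Camera gave adjusted p-values of 9.40e-05, 0.00556 and 0.00158 for these lists (adjusted p = 0.551, adjusted p = 0.547 and adjusted p = 0.473 with an estimated correlation).

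Single libraries carried much of these falls. Without control 1 the interferon median was -0.32, the Schwann median -0.38 and the log2 fold change of Pmp22 -0.60, and without control 3 the erythroid median and the log2 fold change of Hba-a1 were both -0.80. The interferon list score was 1.05 in control 1 against -0.38 and -0.67 in the other controls, and the Schwann score 1.07 against -0.56 and -0.50. The erythroid score was 0.77 in control 3 against -0.05 and -0.71. Interferon genes that fell numbered 3 without control 2 and 1 without control 1 or any knockout. Schwann markers that fell numbered 1 without control 1 or control 3, 4 without control 2 and 0 without any knockout (Pmp22 adjusted p = 0.0613 to 0.0873). Erythroid genes that fell numbered 0 without control 1 or control 3, 3 without knockout 1, 2 without knockout 2 and 1 without knockout 3 or knockout 4.

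**Figure D4:**
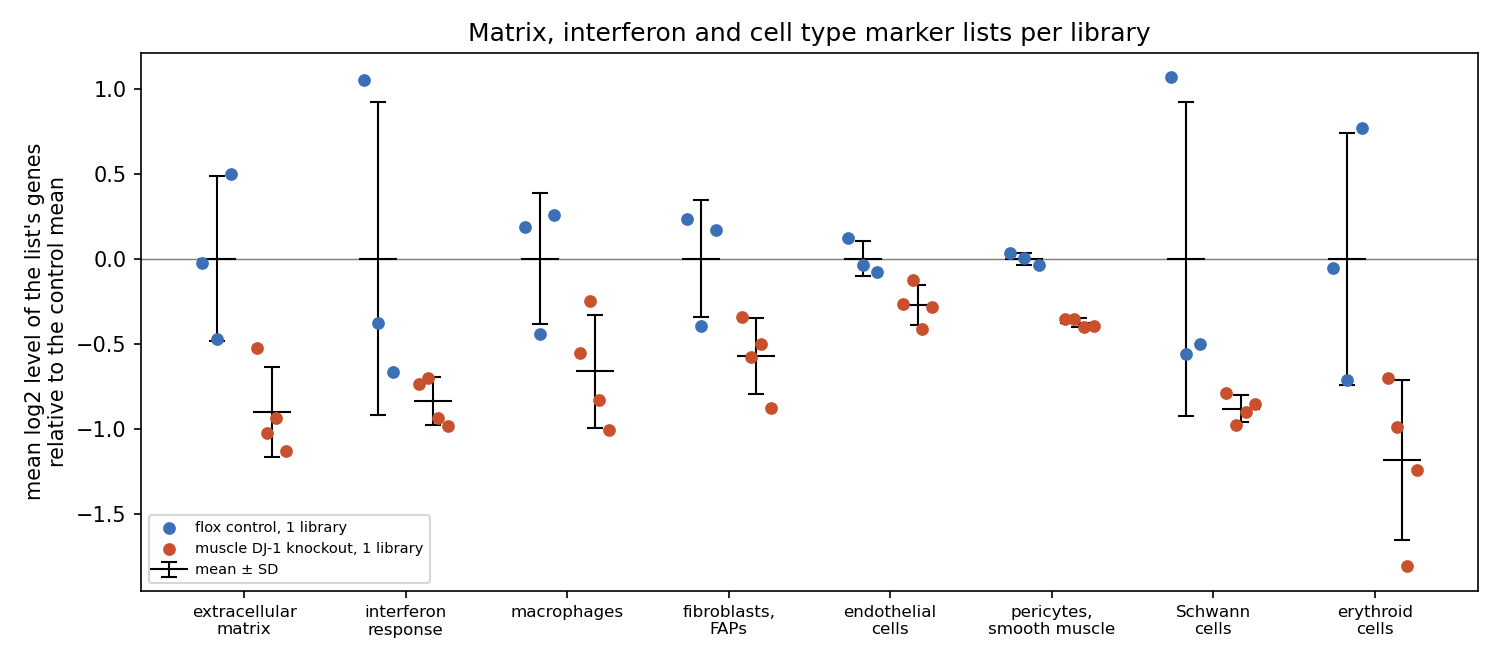
Mean log2 level of the genes of matrix, interferon and cell type marker lists relative to the control mean (y axis) in each control and knockout library (points), with the mean and SD of each group in black. Control 1 stands at 1.05 for interferon response and 1.07 for Schwann cells, above all other libraries, and the groups overlap in the macrophage, fibroblast and erythroid lists.

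Of the genes with the largest rises, Slc25a25, a mitochondrial carrier of ATP and magnesium, rose from 20.5 ± 0.656 to 76.8 ± 13.7 CPM, by 1.91 on the log2 scale (SE 0.14, adjusted p = 0.00103). Mical2, an enzyme that oxidises actin, rose by 1.71 (SE 0.188, adjusted p = 0.00298) and Aacs, which turns ketone bodies into lipid precursors, by 1.95 (SE 0.247, adjusted p = 0.00376). Tmem132b, the cell adhesion gene Cdh4 and Enox2 rose by 2.68, 2.13 and 1.71 (adjusted p = 0.00875, 0.0119 and 0.00921). Cebpd, a transcription factor induced by glucocorticoids and inflammation, rose by 2.08 (adjusted p = 0.0153) and the kinase gene Prkcd by 1.80 (adjusted p = 0.0155). Cebpd was not called without control 1 (0.0563) or control 3 (0.0602), nor Prkcd without control 2 (0.0548) or control 3 (0.0615). The largest rise was that of Cacna1i, a T-type calcium channel, at 3.24 (SE 0.798, adjusted p = 0.0295) from 0.452 ± 0.217 to 4.33 ± 4.17 CPM. Its call ended without control 1 (0.0969), control 2 (0.0744), control 3 (0.0797) or knockout 3 (0.0522), and its log2 fold change was 2.29 without knockout 2. Ddit4 completes the 10. Counts of Slc25a25 in 5 libraries and of Cebpd in 6 were not whole, so both have reads shared with similar genes.

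The largest falls after that of Postn, whose size rested on control 3 (-2.39 without it), were those of Masp1, a protease of the complement system, at -2.79 (SE 0.245, adjusted p = 0.00131) and Cilp, a cartilage and matrix protein, at -2.76 (SE 0.37, adjusted p = 0.00452) from 52.6 ± 11.6 to 7.74 ± 4.32 CPM. Dach2, a transcriptional regulator that acts in the response of muscle to nerve, fell by 2.56 on the log2 scale (SE 0.322, adjusted p = 0.00367). Ldhb, the lactate dehydrogenase of oxidative tissue, fell from 246 ± 32.9 to 50.3 ± 24.8 CPM, by 2.29 (SE 0.433, adjusted p = 0.0124). The Wnt antagonist Frzb fell by 2.27 (SE 0.289, adjusted p = 0.00376). The mitochondrial carrier Slc25a34 fell by 2.39 (adjusted p = 0.0158, which became 0.0526 without control 2). Myl2, the slow regulatory myosin light chain, fell by 2.33 (adjusted p = 0.0407) and was not called without control 1 (0.0830), control 2 (0.0968), control 3 (0.0944), knockout 2 (0.0693) or knockout 4 (0.0632). Park7 and Myh2 complete the 10.

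Of the 37 lists tested, 23 were called by camera with the preset correlation, 6 higher and 17 lower. With an estimated correlation camera called 0 (smallest adjusted p = 0.227, with 4 lists at an unadjusted p under 0.05), and fry called 15, of which 14 were among the 23. The 9 that fry did not call were the proteasome, ribosomal, immediate early, interferon, macrophage, fibroblast, adipocyte, Schwann and erythroid lists (fry adjusted p = 0.0612 to 0.230). Of the 131 named genes that were called, 67 kept their call without each of the 7 libraries in turn.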

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

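Of the tests in this part, the one that sets the mitochondrial DNA mRNAs against all other genes was chosen after the result was seen.

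In 9 named genes 1 knockout library stood far from the other 3, out of 184 groups of 4 libraries examined. Chance gives about 1 in 20 such groups, which is about as many as were seen, so these libraries may stand apart by chance alone. Cacna1i, the T-type calcium channel, read 10.5 CPM in knockout 2 against 1.92 to 2.87 in the others. Periostin (Postn) read 3.56 in knockout 1 against 0.757 to 1.22. Masp1 read 1.37 in knockout 4 against 0.597 to 0.685. Ldhb read 13.2 in knockout 3 against 60.0 to 65.1. The proteasome subunit Psmd8 read 271 in knockout 2 against 323 to 333, and Psma5 66.0 in knockout 3 against 56.5 to 57.6. Phospholamban (Pln) read 0.762 in knockout 1 against 1.52 to 1.63. The chaperone Cryab read 817 in knockout 1 against 452 to 499. The fatty acid binding protein Fabp4 read 114 in knockout 1 against 77.4 to 81.4.

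The mRNAs of mitochondrial DNA and the nuclear respiratory chain subunits fell together. If a few abundant nuclear genes such as Myh4 had only taken more of the counts, all other genes would have lost share alike, but the 13 mRNAs lay below the median of all other tested genes (difference -0.81 on the log2 scale, the same under any scaling of whole libraries), with every knockout library below every control library, which argues against that as the whole cause. Loss of whole mitochondria or of oxidative fibres may contribute. The nuclear subunits lay above the mRNAs by 0.41, between the bounds set before the test. In that difference every knockout library (0.275 to 0.539) lay above every control library (-0.0931 to 0.0713), so the mRNAs fell further than the subunits. As the difference did not reach the upper bound, such a loss and a change of mitochondrial transcription cannot be told apart. The mitochondrial scores of knockout 1 to 4 were -0.73, -0.89, -0.96 and -0.59. An effect of the genotype on mitochondria stays open, as a hypothesis that these data do not test apart from fibre type.

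Of 15 slow fibre genes 9 fell, and Myh4 rose. Less slow muscle in the knockout samples, through dissection or through the genotype, may account for the slow genes: 6 genes restricted to slow fibres, of which only Myl2 was called (adjusted p = 0.0667 to 0.165 for the others), differed by no more than 0.19 in log2 fold change, and the list score of every knockout lay below every control. That test was not sharp, since the standard error of the difference between the extremes was 1.03. Less slow or red muscle stays open for the rise of Myh4 (1.11) too, beside which the fast gene Actn3 rose by 0.74 (adjusted p = 0.0214, not called without control 1 at 0.0867 or control 2 at 0.0738). Whether less slow or red muscle bears on the rises of Fbxo32, Trim63 and glycolysis genes was not tested. Reads shared between myosins were not tested as a cause, and an effect of the genotype on fibre type stays open and untested.

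Some markers of fibroblasts, vessels, macrophages and Schwann cells fell (4 of 12, 6 of 12 pericyte and 2 of 12 endothelial, 3 of 15 and 2 of 10). A smaller share of non-muscle cells may be the source. It would lower all their markers alike only if every cell type fell by the same share, which the test assumed. The medians of 5 marker lists ran from -1.27 (Schwann cells) to -0.29 (endothelium), or -0.38 and -0.19 without control 1, a difference of 0.98 over all libraries, but the libraries of both groups overlapped in that difference (0.608 in control 2 against 0.600 in knockout 1), so a smaller share of these cells and changes within them cannot be told apart. Samples that differed in how much nerve or fascia was taken would also fall under this, and the labels give no batch or dissection record. An effect of the genotype on these cells stays open.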

How the results depend on the processing

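The GC content and length offsets and the run without abundant genes were chosen after seeing the data, and the other alternatives before the data were examined. Park7 kept its direction and its call in all 17 alternatives (log2 fold change -2.77 to -2.64). No gene called both here and in an alternative fit over all genes changed sign. With RLE or upper quartile scaling, no filter, a mean count filter, DESeq2, voom, a robust prior, GC and length offsets or without abundant genes, 1637 to 2354 genes were called, with 33.2% of them higher under upper quartile scaling. Between libraries left out in turn the calls ran from 793 to 2057 (258 to 966 higher and 528 to 1091 lower), and calls over 1.5-fold from 582 to 1064, with fewer samples in each of these fits. A term for the replicate number on replicates 1 to 3, which uses 6 libraries, called 1262 genes (567 higher, 695 lower), 1130 of them among the 1998. The deviations of same-numbered libraries correlated by 0.0945, 0.134 and 0.0854 across genes, so the numbers were not taken to pair the samples, although each control correlated best with its own number. A test against a 1.2-fold change (glmTreat) called 552 genes. Camera called 21 to 25 lists in the other settings, 0 with an estimated correlation, and fry called 15. The first component of the 500 most variable genes held 55.4% of the variance.

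Over all alternatives the named genes gave 2047 results with the same direction and side of the threshold, 326 that were no longer called, 9 newly called and 3 with the opposite direction. The lists gave 715, 35, 10 and 16. None of the opposite values was called and the cause was not tested. Median log2 fold changes that turned were those of the integrated stress response with upper quartile scaling (-0.029) and no filter (-0.0071), and of cell cycle genes with upper quartile scaling (-0.030), no filter (-0.29), voom (-0.055) and the replicate term (-0.063). With libraries left out in turn, list medians ran from -0.039 (without knockout 2) to 0.138 for the integrated stress response, from -0.070 (without knockout 3, also negative without knockouts 2 and 4) to 0.104 for the cell cycle, from -0.018 (without control 1) to 0.102 for ER chaperones, from -0.341 to 0.013 (without control 2) for heat shock, from -0.159 to 0.039 (without control 2) for satellite cells, from -1.93 to 0.648 (without control 3) for tenocytes, from -0.013 (without knockout 2) to 0.086 for antioxidant genes and from -0.102 (without knockout 2) to 0.162 for inflammatory genes. Ppargc1a ran from -0.149 (without knockout 2, also negative without control 3) to 0.182 and Csf3r from -0.591 to 0.103 (without control 3). Postn and Cryab, called without each library, were not called with the replicate term (adjusted p = 0.0807 and 0.07). Foxo1 was called with DESeq2 (adjusted p = 0.0454) and with the replicate term (0.0265), against 0.115 here. Without abundant genes 22 lists were called, as the mitochondrial DNA mRNAs were absent. In the simulation, where fewer genes changed than were called here, the test recovered 39.1% of 1.5-fold changes. A gene that did not pass may still have changed by that much, but the share missed in these data is not known.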

Other observations

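No test in this part was chosen after its result was seen, but Per3 and the other genes nearest Park7 were singled out afterwards.

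Of 33 antioxidant and NRF2 target genes 3 rose, Txn1, Pgd and Keap1, and 9 fell (7 and 9 adjusted over the list alone). Cat, catalase, fell by 1.05 on the log2 scale (SE 0.154, adjusted p = 0.00641), Sod3, the secreted superoxide dismutase, by 1.33 (SE 0.186, adjusted p = 0.00533) and Sod2, the mitochondrial one, by 0.46 (SE 0.0709, adjusted p = 0.0068). Whether these falls are separate from those of mitochondrial, slow fibre and matrix genes was not tested. The list median (0.07) and mean (0.02) were positive whereas camera pointed down (adjusted p = 0.908). The number that fell was 5 without control 2 or knockout 3 and 4 without control 3, and the number that rose was 1 without control 1 or control 2 and 5 without knockout 1. Of 20 genes of the integrated stress response 4 rose and 1 fell (6 and 2 adjusted over the list alone). The lipoprotein receptor gene Vldlr rose by 0.94 (SE 0.0974, adjusted p = 0.00239) and Psat1, an enzyme of serine synthesis, fell by 1.32 (adjusted p = 0.0150, which became 0.0531 without control 2 and 0.0505 without control 3). That list's median was 0.02, its mean -0.01 and its camera direction up (adjusted p = 0.486), and 2 of its genes rose without control 1, knockout 3 or knockout 4 and 1 without control 3, 0 fell without control 3, and 2 fell without knockout 2. Of 19 ER chaperones 0 passed by edgeR, over all genes or adjusted over the list alone (3 at an unadjusted p under 0.05, 0 by DESeq2 or voom, 1 without knockout 2), with Sel1l nearest at 0.25 (adjusted p = 0.0796) and a list median of 0.06 (camera adjusted p = 0.486).

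Of 14 heat shock genes 3 fell (3 adjusted over the list alone, camera adjusted p = 0.240). They were the small heat shock protein genes Hspb6 at -1.04, Cryab at -1.38 and Hspb7 at -1.38 (adjusted p = 0.0162, 0.0163 and 0.0325). Whether their falls are separate from that of slow fibre genes was not tested. Cryab kept its call without each library but not with the term for the replicate number (0.07), Hspb6 lost it without control 2 (0.0518) and Hspb7 without control 2, control 3 or knockouts 2 to 4 (0.0536 to 0.105). Of 20 denervation and neuromuscular junction genes 2 rose and 5 fell (2 and 6 adjusted over the list alone, median -0.30, camera adjusted p = 0.126). Lrp4, the agrin receptor, fell by 0.73 on the log2 scale (SE 0.136, adjusted p = 0.0116) and the neonatal myosin Myh8, which shares reads with other myosins, by 1.67 (SE 0.23, adjusted p = 0.00496). The genes that fell numbered 3 without control 1, control 2 or knockout 3 and 2 without control 3, and 1 rose without control 1.

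Of 18 clock genes 3 rose (3 adjusted over the list alone, median 0.26 and 0.125 to 0.378 with 1 library left out, camera adjusted p = 0.154, 0.0344 without control 3 and 0.0162 without knockout 2), including the repressor Cry1 by 0.52 (adjusted p = 0.0186, which became 0.0705 without control 1, 0.0591 without control 2 and 0.0513 without knockout 3). The number was 1 without control 1, control 3 or knockout 1, 0 without control 2 or knockout 3 and 6 without knockout 2. Per3, a clock gene on chromosome 4 near Park7 that was singled out after its values were seen, had a log2 fold change of -0.93 (adjusted p = 0.0940, which became 0.0306 without control 1). Of 18 immediate early genes 2 rose (2 adjusted over the list alone, median 0.50), Klf6 by 0.78 and Klf4 by 0.55 (adjusted p = 0.0137 and 0.0167). Camera gave 0.0112 (0.0537 without control 3, adjusted p = 0.522 with an estimated correlation), and 0 of these genes rose without control 1 (Klf6 0.0543, Klf4 0.0585) or control 3 (0.0575 and 0.0653) and 5 without knockout 2. Of 14 inflammatory genes 2 rose (2 adjusted over the list alone, camera adjusted p = 0.575), Relb by 0.85 and Il1r1 by 0.56 (adjusted p = 0.0270 and 0.0447), and 0 or 1 without each library in turn. Of 11 cell cycle genes 1 fell (1 adjusted over the list alone), the spindle motor Kif11, at -1.18 (adjusted p = 0.0167, which became 0.0653 without control 3), with a median of 0.02, a mean of -0.12 and a camera direction of down (adjusted p = 0.684, fry 0.0237).

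Of 10 satellite cell markers and myogenic regulators 0 passed by edgeR, over all genes or adjusted over the list alone (3 at an unadjusted p under 0.05, 0 by DESeq2 or voom, 1 without knockout 2 or knockout 4, median -0.09, camera adjusted p = 0.486). Nearest was Vcam1, at -0.57 (adjusted p = 0.0566). Of 6 tenocyte markers 1 fell (1 adjusted over the list alone, median -1.28, camera adjusted p = 0.486, 0.0443 without control 2, but a median of 0.65 without control 3), Thbs4 by 1.6 on the log2 scale (adjusted p = 0.0233, which became 0.0671 without control 3 and 0.0610 without knockout 3, with a log2 fold change of -1.02 without control 3), and 3 fell without control 2. Of 4 sex-linked genes, all on the Y chromosome, 1 fell (1 adjusted over the list alone, median 0.05, mean -0.02, camera direction up, adjusted p = 0.957), Kdm5d by 0.39 (adjusted p = 0.0337, not called without control 2, control 3, knockout 3 or knockout 4, 0.0712 to 0.125). Of the 2 neutrophil markers tested, Mmp9 was at 1.64 and Csf3r at -0.30 and neither passed (adjusted p = 0.0977 and 0.721, with 1 higher adjusted over the list alone), too few for a list test. Mmp9 was called without knockout 1 (0.0355). The number of lymphocyte markers over the filter was 0.

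A floxed allele can carry along variants of the strain in which it was made, and these may change genes near it. Controls that carry the same floxed allele would share such variants. The groups would then differ in them mainly if the controls lack the allele, as the label wild type leaves possible. Of 105 tested genes within 5 Mb of Park7, 11 were called, against 108 of 704 on the rest of chromosome 4. The odds ratio was 0.646 (95% interval 0.302 to 1.26, 2-sided Fisher's exact p = 0.237), which argues against an excess of changed genes over that whole window. Within 1 Mb, 1 of 9 was called, but among the 5 genes nearest Park7, looked at after their values were seen, 4 lay near the threshold without passing: Camta1 (adjusted p = 0.0503), Vamp3 (0.0530), Rere (0.0890) and Per3 (0.0940). Effects of linked variants on the closest genes therefore stay open, above all for the case of controls without the floxed allele.

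The 7 libraries can be split in 35 ways into groups of 3 and 4. The real split called 1998 genes and the highest other 42, so that 1 of the 35 splits, the real one, called as many. That is the smallest share that 35 splits can give (2.86%), so chance is unlikely for that count but not excluded. Over 1.5-fold the numbers were 1009 and 39, again with 1 of the 35 as large. For lists the real split called 23 and the highest other 25, with 3 of the 35 as large, so chance cannot be excluded for the number of lists.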
